A study of Homo sapiens with 6 samples.

How the data were processed

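RNA sequencing of THP-1 cells, a human acute monocytic leukemia line widely used as a model of monocytes, was analysed for 6 libraries, 3 control and 3 hypoxia. Per the labels, the cells were grown in DMEM with fetal bovine serum and total RNA was taken with a column kit. The oxygen level and the length of the hypoxia treatment are not given in the sources used here. Groups and replicate numbers were taken from the sample titles and treatment labels.

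The deposited matrix holds 62703 Ensembl genes with a whole-number read count and an FPKM value for each library, per the file headers. The authors deposited the counts without normalization. The FPKM values deposited beside them follow each library's own total gene count, mitochondrial reads included, and were not used in any test. Per the submitters' processing notes, CASAVA 1.8, HISAT2, SAMtools 1.3.1 and edgeR were used with the GRCh38 build. The counting tool, its strand setting and the annotation release are not given in the sources used here, so reads from overlapping genes or near-identical copies cannot be told apart in these counts. Gene symbols were matched by Ensembl identifier for 62625 of the 62703 genes. Positions and gene types come from GENCODE release 29, which is on the same build and held 58279 of the identifiers.

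Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with the filterByExpr rule (minimum count 10), libraries were scaled by trimmed mean of M-values (TMM), and hypoxia was compared with control by the quasi-likelihood F test with Benjamini-Hochberg (BH) adjustment at 0.05. Fold changes are fitted log2 ratios of hypoxia to control, and their standard error (SE) is the absolute log2 fold change divided by the square root of F. Expression levels are TMM-normalised CPM, the usual depth-scaled counts, given as mean ± SD over the libraries of a group. The size filter of 2-fold is applied after the test and is not a test against that fold. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

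There were 30 gene lists with 684 names, of which 1 matched no gene. Older symbols were looked up among RefSeq synonyms, and a gene listed under an older and a newer symbol was counted once. Lists with 5 or more tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with BH adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and compares the list with no other genes. Its mixed form tests for changes in either direction. Member counts are given over all genes tested and adjusted over the list alone. The tests, the lists, the rule for naming genes and the first set of alternatives below were chosen before the data were examined.

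Genes are named by this rule. The first part is 11 genes of the study question. The second is up to 10 genes per direction by fitted fold change, with adjusted p under 0.05, mean CPM of 5 or more and groups that do not overlap. The third is up to 4 members per list that passed the test, by size of change at a mean CPM of 1 or more, or, where fewer than 2 passed, the members with the highest mean CPM. Leaving out each library was chosen in advance. Giving the fit without hypoxia replicate 3 its own description, and applying the rule to it, was decided after the data were seen.

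Library totals ran from 12954897 to 23869092 reads on genes. In the shallowest library a floor of 3 counts corresponds to 0.518 normalised CPM. Intervals on read shares are exact binomial intervals at 95% and cover counting error only. Counts were simulated with the real means, library sizes and spread, and the changed genes were taken from those with a mean CPM of 5 or more. Each gene and library was drawn independently, so a joint shift of a whole library, as in hypoxia replicate 3, was not simulated. The test over 6 libraries (17454 genes in that run) recovered 42% of 100 genes changed 4-fold. It recovered 0% of 100 genes changed 2-fold, with 3 false calls among 45. Without hypoxia replicate 3 (18199 genes in that run) it recovered 72% and 6%, with 10 false calls among 88.

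Alternatives chosen at that time were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, other count filters, the replicate number as a block, leaving out each library in turn, leaving out mitochondrial genes, thinning to the smallest library, and glmTreat against a fold of 1.5. Alternatives added after seeing the data were library quality weights in limma-voom, robust edgeR, and fits without the libraries that stood apart.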

Results

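The series measured gene transcripts by RNA sequencing in THP-1 monocytic cells under control culture or hypoxia, with 3 libraries in each group. Its title concerns hypoxia, the energy-sensing kinase AMPK, and pyroptosis driven by the NLRP3 inflammasome in periodontitis. Reads on genes amounted to 22891164, 20670634 and 18170695 in control replicates 1 to 3 and to 23869092, 22105340 and 12954897 in hypoxia replicates 1 to 3. Genes of the mitochondrial genome took 15.6% to 16.7% of the reads in the controls. They took 7.43% and 8.59% in hypoxia replicates 1 and 2, but 66.1% in hypoxia replicate 3 (95% interval 66.1% to 66.2%, exact binomial), which left that library 4387496 reads on other genes. Over non-mitochondrial genes, hypoxia replicates 1 and 2 correlated at r = 0.980 (log2 CPM, across genes, which are not independent replicates), whereas hypoxia replicate 3 correlated with them at 0.841 and 0.833. Control pairs lay between 0.931 and 0.951. Controls against hypoxia replicates 1 and 2 lay between 0.915 and 0.938, which overlaps the control pairs. Control replicate 3 correlated with hypoxia replicates 1 and 2 at 0.936 and 0.938, and with control replicate 1 at 0.931. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 23.0 or more.

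**Figure D1:**
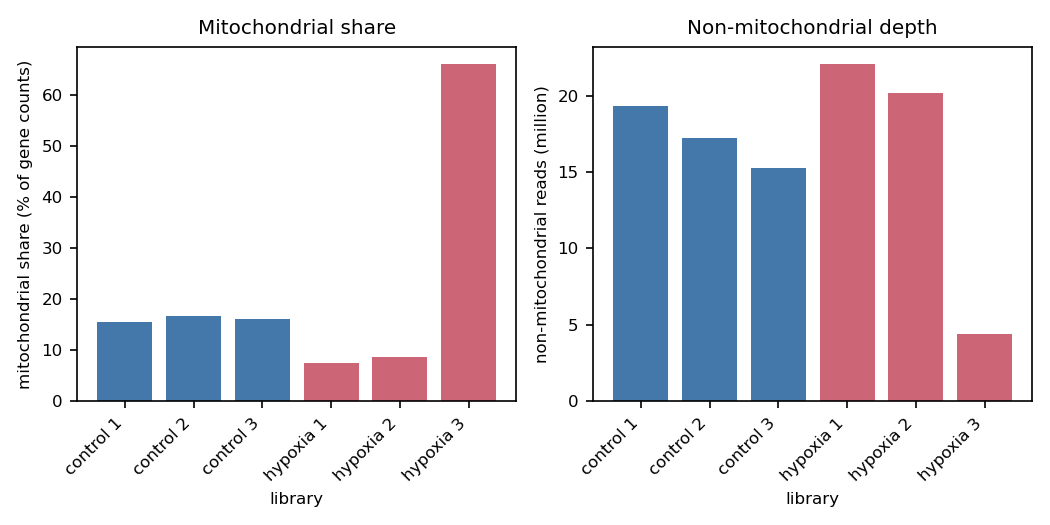
Share of gene counts on mitochondrial genes (left, percent) and reads on all other genes (right) in each of the 6 libraries, control in blue and hypoxia in red. Hypoxia replicate 3 has 66.1% mitochondrial reads and 4387496 other reads, against at most 16.7% and at least 15256838 in the other 5 libraries.

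Across all 6 libraries, 23 genes rose and 3 fell in hypoxia out of 17963 tested, and each of the 26 changed at least 2-fold. The largest rise was in ABCG1, a cholesterol exporter of macrophages, from 1.41 ± 0.886 to 52.8 ± 8.78 CPM (SD, n = 3 each), a fitted 37.5-fold change (log2 fold change 5.23, SE 0.56; edgeR quasi-likelihood, BH adjusted p = 0.0424). Interferon-induced IFIT2 and IFIT3 rose 9.69-fold and 7.15-fold. The Src-family kinase gene FGR rose 6.73-fold and the inositol phosphate kinase gene ITPK1 rose 6.57-fold. ISM1 rose 7.78-fold, TNFAIP8 6.09-fold, NDST1 5.40-fold, MRAS 5.19-fold and RAB11FIP4 4.58-fold. Of the genes that fell, IRAK3, a negative regulator of Toll-like receptor signalling, went from 52.1 ± 2.68 to 15.9 ± 1.11 CPM (SD, n = 3 each; log2 fold change -1.72, SE 0.17; edgeR quasi-likelihood, BH adjusted p = 0.0424). The nucleotide exporter gene ABCC5 fell from 45.5 ± 3.57 to 12.6 ± 1.53 CPM (SD, n = 3 each). The remaining gene was the pseudogene FCF1P2, at 3.91 ± 0.224 and 0.122 ± 0.0492 CPM (SD, n = 3 each), which lies outside the naming rule, was singled out after its values were seen, and may share reads with near-identical copies. On GRCh38, ABCG1 (ENSG00000160179) lies on chromosome 21 from 42199689 to 42297244, IFIT2 (ENSG00000119922) on chromosome 10 from 89283694 to 89309276, and IRAK3 (ENSG00000090376) on chromosome 12 from 66188879 to 66254622.

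All 26 genes also passed with DESeq2 and with limma-voom. A total of 3444 genes had an unadjusted p under 0.05, and groups did not overlap for 5256 genes (29.3%, against 10% for libraries without any structure). That share was not computed for other splits of the libraries, so it does not single out the treatment. The count of called genes rests on the scaling and on which libraries enter. Scaled by library size only, edgeR called 0 genes higher and 0 lower. Without hypoxia replicate 3 the count was 1332 higher and 913 lower of 18822 tested. It was 0 in both directions in edgeR without control replicate 1, 2 or 3 or hypoxia replicate 1, with 3157, 2201, 2123 and 2575 genes at an unadjusted p under 0.05. Without hypoxia replicate 2 it was 1 higher and 0 lower, with 2499 at an unadjusted p under 0.05. DESeq2 on all 6 libraries called 826 higher and 549 lower.

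Leaving out hypoxia replicate 3, which was given this room only after its values were seen, 760 genes rose and 566 fell at least 2-fold, and all 26 genes above changed in the same direction. The macrophage scavenger receptor gene MSR1 rose 17.1-fold in that fit (log2 fold change 4.10, SE 0.14; edgeR quasi-likelihood, BH adjusted p = 0.00623). MSR1 stood at 101 and 108 CPM in hypoxia replicates 1 and 2, at 24.7 CPM in hypoxia replicate 3, and at 6.09 ± 0.445 CPM in the controls (SD, n = 3). The homeobox gene DLX3 rose 17.3-fold, with 10.0 CPM in hypoxia replicate 3 against 4.54 ± 2.90 CPM in control (SD, n = 3). The phosphatase gene ACP3 rose to 222 and 232 CPM in hypoxia replicates 1 and 2, with 14.1 CPM in hypoxia replicate 3 and 14.2 ± 11.2 CPM in control (SD, n = 3). CSF1, the macrophage growth factor, rose 11.8-fold and C5AR1, the receptor for complement C5a, rose 8.15-fold, and both were highest in hypoxia replicate 3 (271 and 129 CPM). Among the genes that fell, NKD2, an antagonist of Wnt signalling, dropped 7.50-fold, the peptide transporter gene SLC15A2 7.43-fold and the zinc finger gene ZNF324 5.95-fold. The metallothionein gene MT2A fell by 2.69 on the log2 scale (SE 0.45; edgeR quasi-likelihood, BH adjusted p = 0.0273), with 33.3 CPM in hypoxia replicate 3 against 5.34 and 4.13 CPM in hypoxia replicates 1 and 2. MSR1, DLX3, ACP3, CSF1, C5AR1, NKD2, SLC15A2, ZNF324 and MT2A did not pass with all 6 libraries in edgeR (NKD2 did without a count filter, at an adjusted p of 0.0470). On all 6 libraries DESeq2 called each of them except MT2A, limma-voom called C5AR1, NKD2 and ZNF324, and limma-voom with quality weights called every one.

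Only transcripts were measured, so protein levels and the activity of AMPK, HIF or the inflammasome were not observed. Within that limit, the question in the title was read through 11 genes, none of which passed with all 6 libraries in edgeR. Of the 10 that were tested, 3 had an unadjusted p under 0.05, and DESeq2 called HIF1A. NLRP3 (ENSG00000162711, chromosome 1 from 247416156 to 247449108), the inflammasome sensor, stood at 35.6 ± 1.62 CPM in control and at 113, 111 and 25.4 CPM in hypoxia replicates 1 to 3 (log2 fold change 1.23, SE 0.52; edgeR quasi-likelihood, BH adjusted p = 0.265). Without hypoxia replicate 3, NLRP3 rose 3.15-fold (log2 fold change 1.65, SE 0.11; edgeR quasi-likelihood, BH adjusted p = 0.0125), the only gene of the 11 to pass in that fit. CASP1, the protease that matures interleukin 1 beta, was at 21.8 ± 2.67 in control and 15.2 ± 1.67 CPM in hypoxia, and GSDMD, the pore protein of pyroptosis, was at 62.5 ± 8.43 and 44.2 ± 10.3 CPM (SD, n = 3 each). The adaptor gene PYCARD was at 32.4 ± 18.3 and 28.6 ± 7.77 CPM. IL18 was at 3.08 ± 0.567 and 5.79 ± 1.06 CPM, and TXNIP at 114 ± 16.1 and 158 ± 25.8 CPM. IL1B was at 540 CPM in control replicate 1 against 2472 and 1807 CPM in control replicates 2 and 3, and averaged 1338 ± 245 CPM in hypoxia (SD, n = 3). PRKAA1, a catalytic subunit of AMPK, was at 50.5 ± 13.5 and 38.7 ± 4.42 CPM. PRKAA2, the other catalytic subunit, had 20, 20 and 0 counts in control and 1, 0 and 6 in hypoxia, too few to test with 6 libraries. HIF1A was at 43.9 ± 10.7 and 91.9 ± 26.1 CPM (SD, n = 3 each; log2 fold change 1.06, SE 0.29; edgeR quasi-likelihood, BH adjusted p = 0.137), and EPAS1 at 4.94 ± 1.98 CPM in control and 3.001, 2.767 and 18.80 CPM in hypoxia replicates 1 to 3, so that its log2 fold change turned from 0.69 to -0.77 without hypoxia replicate 3.

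**Figure D2:**
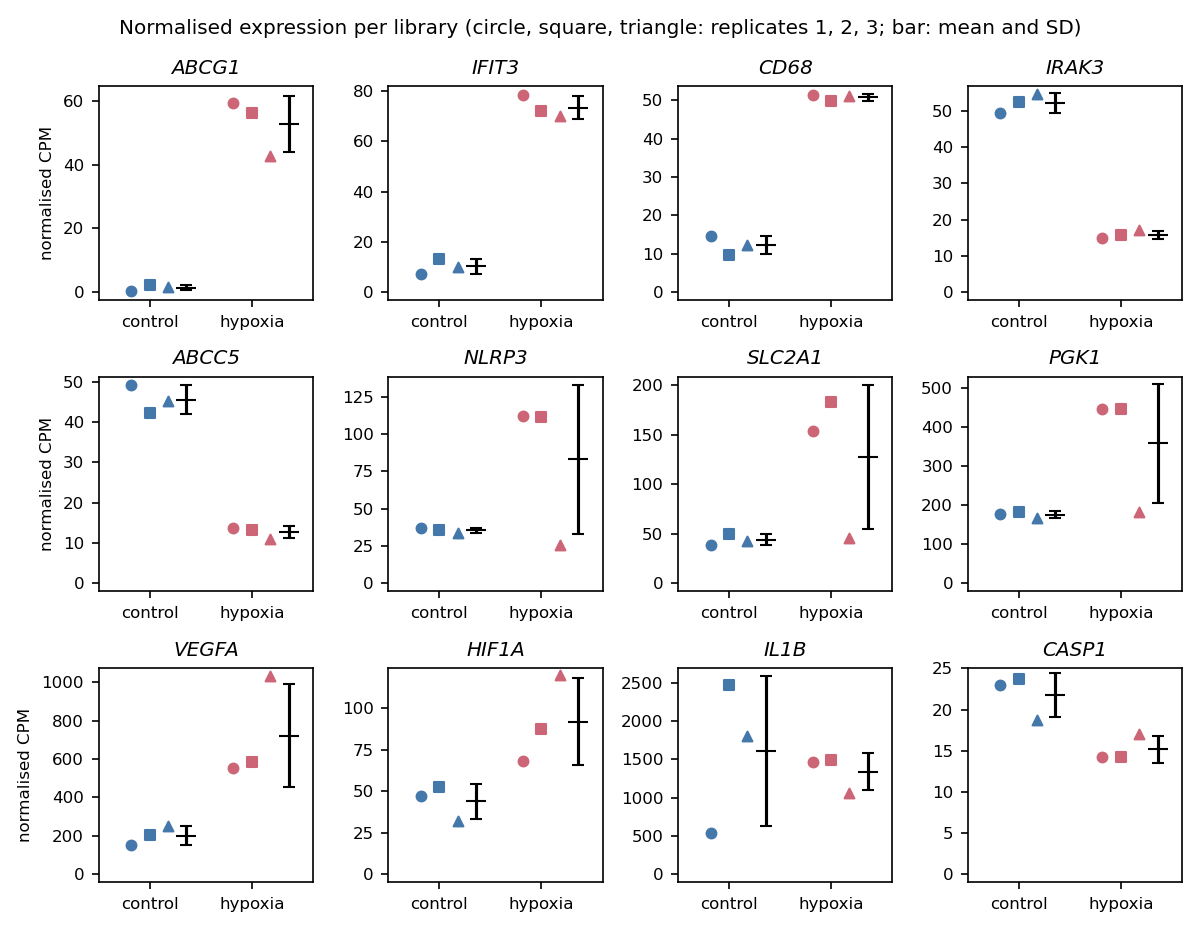
Normalised CPM of 12 genes in each library (circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of each group (n = 3) as a black bar. ABCG1, IFIT3, CD68, IRAK3 and ABCC5 separate the groups in every library, while for NLRP3, SLC2A1 and PGK1 hypoxia replicate 3 (25.4, 45.4 and 182 CPM) lies below or among the controls.

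Neither list drawn from the question was called by camera or by fry in 1 direction (fry, BH adjusted p = 0.115 for the inflammasome list and 0.873 for the AMPK list). Changes in either direction gave lower values, at unadjusted p = 4.07e-05 and 0.00131 with 6 libraries (fry, mixed form). Without hypoxia replicate 3 they were 2.10e-06 and 7.07e-05 (fry, mixed form, unadjusted). That form compares a list with no other genes, so it does not set these lists apart from the rest. In the inflammasome and pyroptosis list, 0 of 21 tested members passed in edgeR with 6 libraries, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05 and 1 called by DESeq2 (median log2 fold change 0.37; camera, BH adjusted p = 0.294, and 0.569 with an estimated correlation). In the fit without hypoxia replicate 3, NLRP3 and NEK7, a kinase that binds NLRP3, rose, and 5 higher and 1 lower passed adjusted over the list alone (camera, BH adjusted p = 0.213). In the list of AMPK subunits, upstream kinases and substrates, 0 of 21 passed in edgeR over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 2 called by DESeq2 (median 0.05 and mean 0.04, with the test's direction downward; camera, BH adjusted p = 0.997, and 0.997 with an estimated correlation). Leaving out hypoxia replicate 3, TBC1D1, MAP3K7 and FOXO3 rose by 1.47, 0.97 and 0.70 on the log2 scale and TSC2 fell by 0.61, with 4 higher and 2 lower adjusted over the list alone (median -0.06 and mean -0.15, with the test's direction upward; camera, BH adjusted p = 0.843).

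Target genes of the hypoxia-inducible factors (HIF) outside glycolysis were higher as a list, with a median log2 fold change of 0.80 over 39 tested members (camera, BH adjusted p = 3.86e-07; adjusted p = 0.0999 with an estimated correlation). With 6 libraries 0 members passed over all genes in edgeR, 11 were higher adjusted over the list alone, 22 had an unadjusted p under 0.05 and DESeq2 called 12. VEGFA, the angiogenic growth factor, was at 201 ± 49.7 CPM in control and 722 ± 267 CPM in hypoxia (SD, n = 3 each; edgeR quasi-likelihood, BH adjusted p = 0.0775), with 552, 585 and 1030 CPM in hypoxia replicates 1 to 3. When hypoxia replicate 3 was left out, 12 members rose and 0 fell, with 18 higher and 2 lower adjusted over the list alone (camera, BH adjusted p = 3.61e-06; adjusted p = 0.280 with an estimated correlation). The rises were led by MIR210HG, the host of microRNA miR-210, by 4.48 on the log2 scale, ZNF395 by 2.76, the adenylate kinase AK4 by 2.23 and ANKRD37 by 2.15. MIR210HG was at 0.863 CPM in hypoxia replicate 3 against 11.4 and 9.70 CPM in hypoxia replicates 1 and 2. The list also holds LOX, a collagen cross-linking enzyme named here after its values were seen, which was high in the libraries with high fibroblast markers, at 16.6, 18.0 and 2.52 CPM in control and at 1.82, 1.28 and 42.1 CPM in hypoxia.

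Genes of glycolysis and glucose uptake were also higher as a list, with a median of 0.55 over 25 members (camera, BH adjusted p = 0.00452; adjusted p = 0.569 with an estimated correlation). With 6 libraries 0 members passed in edgeR, over all genes or adjusted over the list alone, with 8 at an unadjusted p under 0.05 and 2 called by DESeq2. When it was fitted without hypoxia replicate 3, 10 rose and 0 fell (11 higher adjusted over the list alone). They included the glucose transporter SLC2A1 (3.85-fold), PDK1, which restrains entry of pyruvate into mitochondria (log2 fold change 1.55), and the glycolytic enzymes PGK1 (2.54-fold) and PKM (log2 fold change 1.17), and the list was called (camera, BH adjusted p = 5.41e-06; adjusted p = 0.242 with an estimated correlation). SLC2A1 was at 154 and 183 CPM in hypoxia replicates 1 and 2 and at 45.4 CPM in hypoxia replicate 3, against 43.8 ± 5.52 CPM in control (SD, n = 3). The subunits and oxygen sensors of HIF were not called as a list (median 0.32; camera, BH adjusted p = 0.294), and 0 of 10 members passed in edgeR, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2.

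Interferon-stimulated genes had the lowest p of the 30 lists with camera at the preset correlation on all 6 libraries, though not with an estimated correlation, by fry, or without hypoxia replicate 3. All 25 tested members had a positive fold change (median log2 fold change 1.47), IFIT2 and IFIT3 rose over all genes, and 13 were higher adjusted over the list alone (camera, BH adjusted p = 4.85e-17; adjusted p = 0.290 with an estimated correlation). In the fit without hypoxia replicate 3, 5 members rose, among them the deconjugating protease gene USP18 by 2.02 on the log2 scale. Mean log2 CPM of the list was 3.02, 4.64 and 4.40 in the controls and 5.69, 5.47 and 5.96 in hypoxia, so control replicate 1 lay lowest. Targets of NF-kB were higher as a list (median 0.58; camera, BH adjusted p = 0.000588; adjusted p = 0.569 with an estimated correlation). With 6 libraries 0 of the 24 tested NF-kB members passed in edgeR over all genes, 6 were higher adjusted over the list alone, 10 had an unadjusted p under 0.05 and DESeq2 called 6. IL1RN, the interleukin 1 receptor antagonist, and CD83 rose by 2.71 and 2.29 without hypoxia replicate 3. The NF-kB list was not called without that library (camera, BH adjusted p = 0.1003) or without control replicate 1 (camera, BH adjusted p = 0.0956).

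Monocyte and macrophage markers were higher as a list (median 0.28; camera, BH adjusted p = 0.00147; adjusted p = 0.161 with an estimated correlation). The lysosomal glycoprotein gene CD68 rose from 12.3 ± 2.39 to 50.8 ± 0.849 CPM (SD, n = 3 each; log2 fold change 2.05, SE 0.21; edgeR quasi-likelihood, BH adjusted p = 0.0424), and 6 of 26 members were higher adjusted over the list alone. In the fit without hypoxia replicate 3, 6 members rose, including MSR1, the endotoxin co-receptor CD14 (log2 fold change 1.78) and the haemoglobin scavenger receptor CD163 (1.72). Genes of MHC class II presentation were called higher (median 0.69 over 6 members; camera, BH adjusted p = 0.0222; adjusted p = 0.336 with an estimated correlation) and lost that call without hypoxia replicate 3 (camera, BH adjusted p = 0.189) or control replicate 1 (0.0880). Only 6 of the 12 listed genes were tested, and 0 passed in edgeR over all genes. CTSS and IFI30 had log2 fold changes of 2.01 and 1.63, CD74 had 0.36, and the class II chain gene HLA-DRB1 had -0.42. The call is thus no sign that class II molecules rose. Pattern recognition receptors and adaptors were not called (camera, BH adjusted p = 0.740), with IRAK3 lower. TLR4, the endotoxin receptor, and its adaptor MYD88 rose by 1.84 and 1.41 without hypoxia replicate 3. Lymphocyte markers were not called (camera, BH adjusted p = 0.973), and TRAC, the T cell receptor alpha constant gene, was at 102, 101 and 12.2 CPM in hypoxia replicates 1 to 3 against 17.8 ± 0.815 CPM in control (SD, n = 3).

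The mitochondrially encoded respiratory chain reversed its direction with hypoxia replicate 3. Without that library all 13 genes fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.89 (camera, BH adjusted p = 9.12e-09; adjusted p = 0.538 with an estimated correlation). Cytochrome oxidase subunit gene MT-CO1 fell by 1.09 and MT-CYB by 1.02 on the log2 scale in that fit. With all 6 libraries the median was 1.38, 0 of 13 passed in edgeR, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (camera, BH adjusted p = 0.229). A gene to which DESeq2 gave no adjusted p counts as not called, so its 0 is no sign of an unchanged level. The list was called higher without hypoxia replicate 1 or 2 (camera, BH adjusted p = 0.000868 and 0.00268). The nuclear-encoded respiratory chain was not called with 6 libraries (median 0.15; camera, BH adjusted p = 0.553). Fitted without hypoxia replicate 3 it was called higher (median 0.40; camera, BH adjusted p = 0.000287; adjusted p = 0.242 with an estimated correlation), with SDHC of complex II up by 1.42 and COX5A of complex IV by 1.00.

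Stress lists moved in several directions. Immediate early genes, a list set up as a sign of handling stress, were called higher with a median of 1.16 over 24 members (camera, BH adjusted p = 9.67e-09; adjusted p = 0.0999 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower. Whether handling differed between the groups was not tested. The nuclear receptor gene NR4A3 rose by 3.06 and EGR2 by 2.38 without hypoxia replicate 3. Endoplasmic reticulum chaperones were called higher (median 0.25; camera, BH adjusted p = 0.0297; adjusted p = 0.307 with an estimated correlation) but not without control replicate 1 (camera, BH adjusted p = 0.227), and the lectin chaperone genes CANX and CALR rose by 1.64 and 1.36 without hypoxia replicate 3. Targets of p53 were called higher (median 0.33; camera, BH adjusted p = 0.000709; adjusted p = 0.290 with an estimated correlation), and CCNG1 and the pro-apoptotic gene BBC3 rose by 1.33 and 1.02 without hypoxia replicate 3. Antioxidant genes of NRF2 were called lower (median -0.42; camera, BH adjusted p = 0.0132; adjusted p = 0.569 with an estimated correlation) and were not called without hypoxia replicate 3 or control replicate 2 (camera, BH adjusted p = 0.196 and 0.116). Cytosolic heat shock proteins were not called with 6 libraries (camera, BH adjusted p = 0.229). They were called lower without hypoxia replicate 3 (camera, BH adjusted p = 0.0170; adjusted p = 0.607 with an estimated correlation) and without control replicate 1 (camera, BH adjusted p = 0.0461). In the former fit, the co-chaperone genes DNAJB1 and CHORDC1 fell by 1.66 and 1.31. The integrated stress response (camera, BH adjusted p = 0.229), autophagy and mitophagy (0.0671) and effectors of apoptosis and necroptosis (0.740) were not called, although autophagy and mitophagy genes were called higher without hypoxia replicate 2 (camera, BH adjusted p = 0.0293) and, on all 6 libraries, with limma-voom (0.0450), with no count filter (0.0392) and by fry (0.0495), against an adjusted p of 0.384 with an estimated correlation. MTHFD2 of mitochondrial folate metabolism and the autophagy receptor OPTN rose by 1.00 and 1.16 without hypoxia replicate 3.

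Growth lists were lower. Proliferation and mitosis had a median of -0.63 over 22 members (camera, BH adjusted p = 0.000360; adjusted p = 0.569 with an estimated correlation), DNA replication -0.32 (camera, BH adjusted p = 0.00687; adjusted p = 0.684 with an estimated correlation) and ribosome biogenesis -0.32 (camera, BH adjusted p = 0.00229; adjusted p = 0.569 with an estimated correlation). With 6 libraries 0 members of each passed in edgeR, with 3, 3 and 8 at an unadjusted p under 0.05 and 1, 1 and 1 called by DESeq2. None of the 3 lists was called without hypoxia replicate 3 (camera, BH adjusted p = 0.0570, 0.245 and 0.0570). MKI67, a marker of cycling cells, was at 116 ± 10.5 and 60.6 ± 19.2 CPM (SD, n = 3 each). Without hypoxia replicate 3, 1 DNA replication gene rose and 2 fell, and 1 ribosome biogenesis gene rose and 3 fell. The helicase subunit gene MCM6 and NCL, which encodes nucleolin, rose by 0.60 and 0.76, while POLE, a replicative DNA polymerase, and NOP56 of the nucleolus fell by 0.90 and 1.31. Cytosolic ribosomal proteins (camera, BH adjusted p = 0.234), cholesterol synthesis and uptake (0.410) and histone genes (0.950) were not called with 6 libraries. The ribosomal proteins were called lower without hypoxia replicate 1 (camera, BH adjusted p = 0.0441).

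**Figure D3:**
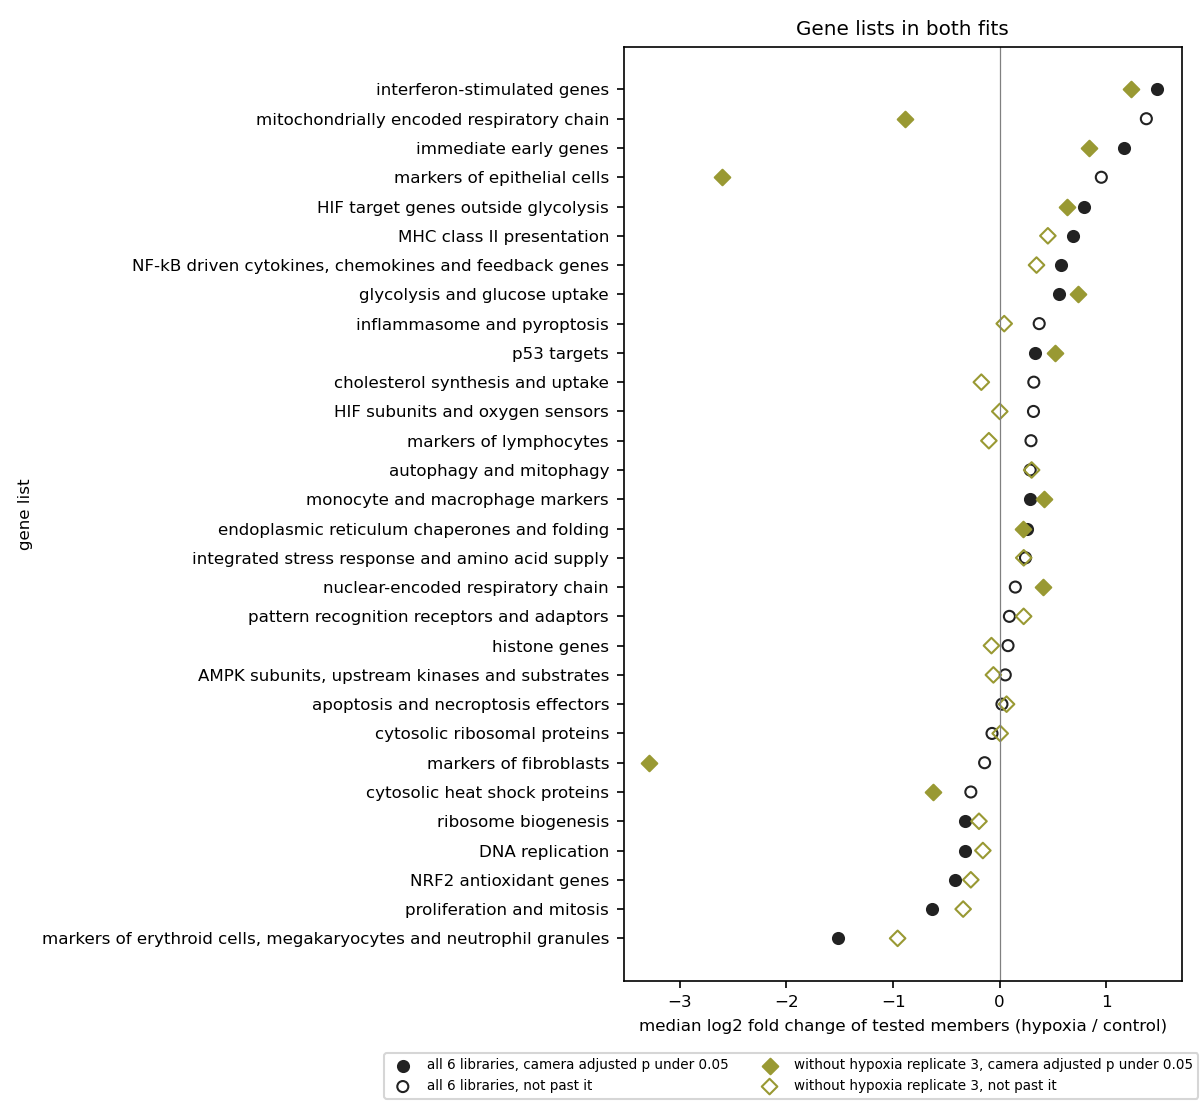
Median log2 fold change (hypoxia over control) of the tested members of 30 gene lists, in the fit of all 6 libraries (circles) and without hypoxia replicate 3 (diamonds), filled where camera's BH adjusted p is under 0.05. In all, 14 lists were called with 6 libraries and 12 without hypoxia replicate 3, and the mitochondrially encoded list lies at 1.38 in the first and at -0.89 in the second.

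Markers of other cell types differed between libraries of the same group. Type I collagen gene COL1A1 was at 299, 320 and 18.1 CPM in control replicates 1 to 3 and at 31.6, 4.89 and 560 CPM in hypoxia replicates 1 to 3. The keratin gene KRT14 was at 2.14, 10.1 and 6.52 CPM in control and at 1.48, 0.561 and 151 CPM in hypoxia. Fibroblast and epithelial markers were not called with 6 libraries (camera, BH adjusted p = 0.294 and 0.740). The fibroblast list was called lower without control replicate 3 (camera, BH adjusted p = 0.0125), and the epithelial list higher without hypoxia replicate 2 (camera, BH adjusted p = 0.0293). Both were called lower without hypoxia replicate 3 (camera, BH adjusted p = 0.0114 and 0.00718; adjusted p = 0.607 for both with an estimated correlation). Markers of erythroid cells, megakaryocytes and neutrophil granules were called lower (median -1.52 over 7 members; camera, BH adjusted p = 0.00887; adjusted p = 0.290 with an estimated correlation). The granule protease gene CTSG was at 366, 75.2 and 100.5 CPM in control and at 29.4, 33.7 and 2.24 CPM in hypoxia, and the list was not called without hypoxia replicate 3, hypoxia replicate 1 or control replicate 1 (camera, BH adjusted p = 0.182, 0.0938 and 0.0702).

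**Figure D4:**
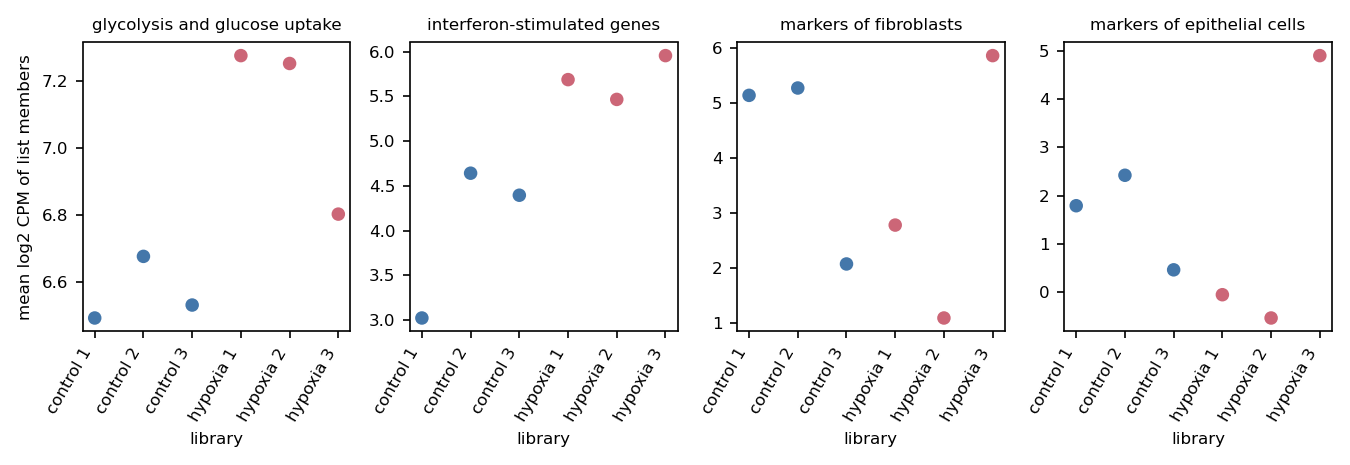
Mean log2 CPM of the members of 4 gene lists in each library, control in blue and hypoxia in red. Fibroblast markers stand at 5.14, 5.28 and 5.87 in control replicates 1 and 2 and hypoxia replicate 3 and at 1.09 to 2.78 in the other 3 libraries, and glycolysis genes in hypoxia replicate 3 (6.80) lie below hypoxia replicates 1 and 2 (7.27 and 7.25).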

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

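The fits with library quality weights, with robust edgeR, and with 3, 4 or 5 libraries under other tools were chosen only after the results were seen. On simulated counts the test recovered 42% of genes changed 4-fold with 6 libraries and 72% without hypoxia replicate 3, so changes of that size can be missed. Those genes had a mean CPM of 5 or more, and genes below that were not among them. No label says that the replicate numbers mark a shared culture or day, so the numbers were not taken to pair the libraries. The same-numbered libraries deviated from their group means with r of 0.034, -0.310 and -0.238 (across genes, which are not independent replicates). Hypoxia replicates 1, 2 and 3 deviated most alike with control replicates 3, 3 and 2 (0.142, 0.270 and 0.302). Within hypoxia, replicate 3 deviated against replicates 1 and 2 (r = -0.866 and -0.885), so these values cannot decide on pairing. With the replicate number as a block, edgeR called 0 genes higher and 0 lower, 0 and 0 of them at least 2-fold, with 2484 at an unadjusted p under 0.05. Where no reason is given below, the cause was not tested.

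Among the scalings, RLE factors gave 31 genes higher and 7 lower and upper-quartile factors 32 and 10, all at least 2-fold, against 23 and 3 with TMM. Scaling by library size only moved the median of all genes to -0.39 (0.03 with TMM) and gave 0 higher and 0 lower (0 and 0 at least 2-fold) in edgeR, with 1982 at an unadjusted p under 0.05. Genes higher in hypoxia numbered 826 with DESeq2 and genes lower 549 (682 and 401 at least 2-fold), with 1 gene of the study question, and limma-voom gave 108 and 36 (108 and 36). A CPM filter gave 36 and 8 (36 and 8), leaving out mitochondrial genes 35 and 7 (35 and 7), thinning to the smallest library 30 and 7 (30 and 7), no count filter 22 and 3, and robust edgeR 20 and 3. The glmTreat test against a fold of 1.5 gave 0 and 0 at least 2-fold, with 1686 at an unadjusted p under 0.05. Library quality weights in limma-voom gave 3291 and 3044 (1483 and 1507) and 5 genes of the study question, with weights of 0.145 for hypoxia replicate 3 and 0.382 for control replicate 1 against 3.29 at most.

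Leaving out each library in turn gave from 0 to 1332 genes higher and 0 to 913 lower, 0 to 760 and 0 to 566 at least 2-fold, 0 to 1 genes of the study question, and 11 to 17 gene lists. The upper ends came without hypoxia replicate 3, except for the lists, where it came without hypoxia replicate 2. Fits with 5 libraries gave 2367 and 1780 with DESeq2 (1174 and 1068 at least 2-fold), 1412 and 796 with limma-voom (829 and 459), and 1376 and 872 without mitochondrial genes (778 and 544). Fits with 4 libraries, without hypoxia replicate 3 and control replicate 1, gave 3093 and 2752 (1401 and 1446). With 3 libraries, control replicate 3 and hypoxia replicates 1 and 2, they gave 2707 and 1956 (1416 and 991), where the lone control is assumed to vary like the hypoxia libraries.

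Of the 14 lists called by camera, 0 were called with an estimated correlation, where the adjusted p was 0.0999 for HIF target genes and 0.569 for glycolysis. The estimate was below the preset 0.01 for monocyte and macrophage markers (-0.0117) and for erythroid, megakaryocyte and neutrophil granule markers (-0.00236). A higher correlation between members is therefore not why those calls were lost. In the rest of the 14 it was above the preset, from 0.0115 for ER chaperones to 0.666 for proliferation and mitosis. Fry called 7 of the 14 and 1 other, autophagy and mitophagy, with 0.197 for glycolysis. The list of AMPK subunits, upstream kinases and substrates was called by direction in none of the fits tried. Its direction turned upward with RLE factors (adjusted p = 0.991), the replicate block (0.910), thinning (0.936), fry (0.873) and quality weights (0.886). The list also turned upward without control replicate 1 (0.854), hypoxia replicate 1 (0.910) or hypoxia replicate 3 (0.843). Its adjusted p ran from 0.811 to 0.910 as each library was left out. Over the same fits the adjusted p ran from 2.13e-07 to 2.13e-05 for HIF target genes outside glycolysis, from 5.41e-06 to 0.0333 for glycolysis, and from 0.213 to 0.480 for the inflammasome list. Directions turned without hypoxia replicate 3 for MT-CO1 and MT-CYB, whose log2 fold changes ran from -1.09 to 1.53 and from -1.02 to 1.94 as each library was left out. They turned likewise for the mitochondrially encoded list (adjusted p from 9.12e-09 to 0.421 over those fits) and the epithelial list (0.00718 to 0.945). Of the other named genes, log2 fold changes turned without hypoxia replicate 3 for EPAS1 (-0.77), KRT14 (-2.61), LOX (-2.99) and PYCARD (0.03). They also turned without control replicate 1 for PYCARD (0.38), without control replicate 2 for IL1B (0.17), without control replicate 3 for LOX (-0.27), and without control replicate 1 or 2 or hypoxia replicate 1 or 2 for COL1A1 (0.21, 0.31, 0.39 and 0.46). Library size only turned EPAS1 (-0.25), LOX (-1.02) and MT-CO1 (-0.06), limma-voom EPAS1 (-0.16), KRT14 (-1.01) and LOX (-1.69), and the replicate block KRT14 (-0.19), LOX (-1.86) and MT-CO1 (-0.05). Quality weights turned EPAS1 (-0.86), LOX (-2.34), MT-CO1 (-0.99), MT-CYB (-0.96) and PYCARD (0.44). They also turned the KRT14 log2 fold change (-2.93), the mitochondrially encoded list (0.0266) and the epithelial list (0.0318). Of the list calls, ER chaperones were lost with upper-quartile factors (adjusted p = 0.0678), library size only (0.187), limma-voom (0.0519), the CPM filter (0.0507) and quality weights (0.130). MHC class II presentation was lost with limma-voom (0.103), the CPM filter (0.0507), fry (0.0514) and quality weights (0.321), and markers of erythroid cells, megakaryocytes and neutrophil granules with limma-voom (0.0519), no count filter (0.177) and quality weights (0.130). Quality weights also lost NF-kB targets (0.365), proliferation and mitosis (0.130) and DNA replication (0.104), and fry lost these (0.299, 0.271 and 0.299), ribosome biogenesis (0.181) and NRF2 antioxidant genes (0.257). Autophagy and mitophagy were gained with limma-voom (0.0450), no count filter (0.0392) and fry (0.0495). Cytosolic heat shock proteins were gained with library size only (0.0340) and quality weights (0.00714), which also gained the nuclear-encoded respiratory chain (0.000741) and fibroblast markers (0.0371). List calls that changed when a library was left out are given with each list in the report.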

Other observations

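Chosen only after the result was seen were the tests of mitochondrial reads, of small non-coding RNA, of a control-state library, of a response to hypoxia in fibroblast markers, and of dilution. The remaining tests were written before their results were seen.

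Several further genes that rose with all 6 libraries were named after their values were seen. IL7R, the interleukin 7 receptor, went from 28.1 ± 3.93 to 117 ± 12.2 CPM, and RCAN1, an inhibitor of calcineurin, from 44.9 ± 5.56 to 204 ± 42.8 CPM (SD, n = 3 each). TLE3, a transcriptional corepressor, went from 16.8 ± 1.41 to 67.8 ± 2.09 CPM, and SARAF, a regulator of store-operated calcium entry, from 31.2 ± 2.09 to 83.1 ± 1.09 CPM (SD, n = 3 each). In these 4 genes hypoxia replicate 3 lay above every control, with RCAN1 at 154 CPM there against 228 and 229 CPM in hypoxia replicates 1 and 2.

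Hypoxia replicate 3 stood apart from hypoxia replicates 1 and 2 over non-mitochondrial genes too (r = 0.841 and 0.833). Leaving out mitochondrial genes raised the calls from 26 to 42, against 2245 without that library. That count could change little, because TMM had already scaled the library by 0.448, so it is no separate test. Depth does not account for the difference: hypoxia replicates 1 and 2 thinned to 4387496 non-mitochondrial reads still correlated at r = 0.960 (SD 0.000427 over 10 thinnings), against 0.835 on average with hypoxia replicate 3. What state of cells or RNA the high mitochondrial share of hypoxia replicate 3 reflects was not tested. A different RNA composition may contribute, as 51 of 67 small non-coding RNA genes were higher there, with a median log2 ratio 1.20 above that of 12904 protein-coding genes. The non-coding RNAs NEAT1 and MALAT1 took 2.46% of its non-mitochondrial reads, against at most 0.119% in any other library. Protein-coding genes took 86.0% of them, against at least 92.5%. Over 2197 genes changed without it, the library lay at a median position of 0.533 between control (0) and hypoxia replicates 1 and 2 (1). The genes were widely spread, with quartiles of 0.0163 and 1.03, and 24.5% of them lay at or under 0. A first bound of 0.25 against a control-state library was wrong, because controls held out of the selection of genes lay at 0.275, 0.363 and 0.128 (control replicates 1 to 3), and hypoxia replicate 3 at 0.505, 0.625 and 0.348 in the same selections of 5733, 8 and 691 genes. Among genes changed at least 4-fold in a selection made without both libraries, hypoxia replicate 3 passed the midpoint towards hypoxia in 3.62 percentage points more genes than control replicate 1 and in 28.8 fewer than control replicate 3, which excluded nothing. The genes were divided by direction after that was seen. Of genes higher in hypoxia, it passed the midpoint in 64.6% of 316 against 42.1% for control replicate 1, and in 71.9% of 96 against 11.5% for control replicate 3, a difference of 22.5 percentage points or more, which argues against a control-state library alone for those genes (only 8 genes could be set against control replicate 2, at 75% and 50%). The genes are correlated and only 3 controls give the spread, and a control-state library mixed with other RNA stays open. For genes lower in hypoxia the values go the other way, at 30.8% of 347 genes against 44.4% for control replicate 1 and at 5.53% of 199 genes against 77.4% for control replicate 3 (a difference of -71.9 percentage points). The selection without control replicate 3 does not mark the control state, since that control itself passed the midpoint in most of its genes, which leaves 1 usable selection that goes towards a control-state library. Fibroblast markers, described below, ran high in control replicates 1 and 2 and hypoxia replicate 3 and low in the other libraries. Genes selected as lower in hypoxia may include such transcripts, and how many do was not counted. For genes lower in hypoxia, a control-state library, a partly responding one and RNA of another cell source cannot be told apart.

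Fibroblast markers were high in control replicates 1 and 2 and hypoxia replicate 3. These libraries come from both groups, so the level of the markers did not follow the treatment. Over 20 further fibroblast genes, not used to find the pattern, the groups accounted for 8.13% of the variance of the mean log2 CPM. That mean was 4.53, 4.60 and 1.73 in the controls and 2.18, 0.97 and 5.00 in hypoxia. Genes that share a pattern running across the groups can only give a low share, so the share is no separate test of a response to hypoxia. RNA or reads of another cell source, such as fibroblasts, is a candidate explanation: of 22 such further genes fixed before their values were seen, 20 were tested, 18 were higher in those 3 libraries and 16 more than 2-fold, with a median log2 ratio of 2.92 against -0.03 for all genes. Of the 20, 4 stood at a log2 CPM of 4 or more in each of the other 3 libraries too. The abundant gene IGFBP5 was at a log2 CPM of 7.21, 7.23 and 7.69 in the 3 libraries and at 1.53 or less in the others, and how such RNA or reads entered the libraries was not tested.

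In hypoxia replicate 3, glycolysis genes lay nearer to control than to hypoxia replicates 1 and 2, at a median position of 0.11, and interferon-stimulated genes at 1.05, the level of hypoxia replicates 1 and 2. The mean log2 CPM of the glycolysis list puts the library further from control than that median does, at 6.80 against 6.49, 6.68 and 6.53 in the controls and 7.27 and 7.25 in hypoxia replicates 1 and 2, and so above every control. The glycolysis median was -0.67 (log2 ratio to hypoxia replicates 1 and 2), at percentile 0.84 of 10000 lists matched on expression. The list was taken up because it lay low in this library, so that percentile cannot exclude a general loss of abundant transcripts. The matched lists fell too, with a median of -0.28 (95% of them from -0.60 to 0.16). Mean log2 CPM also fell for the nuclear-encoded respiratory chain (6.68 and 6.66 to 5.83) and for proliferation and mitosis (4.83 and 4.73 to 3.68). It rose for NF-kB targets (5.03 and 5.12 to 6.41). How much of the glycolysis drop such a loss accounts for stays open. Dilution by RNA from elsewhere stays open. RNA that lacks monocyte and macrophage markers would lower them at least as far as glycolysis genes. The median of 26 such markers was -0.64, a difference of 0.0255 (95% bootstrap interval over genes -0.80 to 1.09), too wide to decide. Whether RNA of other cell types lacks all 26 was not tested. How much interferon-stimulated RNA such a source would bring was not measured, and a weaker glycolytic response to the treatment in that library stays open and untested.

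With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 26 genes, all at least 2-fold, and 2 of the 10 splits called as many for either count, the highest other calling 110. That split set control replicates 1 and 2 and hypoxia replicate 3 against the rest, the same libraries as the fibroblast markers, and points to a structure of the samples that is not the treatment. For gene lists the real split called 14 and the highest other 13, with 1 of 10 as high.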
